A study of Homo sapiens with 37 samples.

How the data were processed

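Total RNA from fresh frozen human liver tissue was extracted with TRIzol, its integrity was measured on an Agilent 2100 Bioanalyzer, and biotin-labelled cDNA was hybridized to Affymetrix Human Gene 1.0 ST arrays, per the labels. The series holds 37 arrays in 5 groups, with 16 of intrahepatic cholangiocarcinoma (ICC), 7 of combined hepatocellular and cholangiocarcinoma (CHC), 2 of hepatic adenoma, 5 of focal nodular hyperplasia (FNH) and 7 of non-tumor liver. All 37 were used. Replicates are numbered within each group by their order in the series, so equal numbers in different groups imply no pairing.

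The deposited values are log2 probe set intensities made by the authors with the robust multi-array average (RMA). Per the submitters' processing notes, GCOS, RMA and Affymetrix Expression Console were used, and their versions, order and settings are not given in the sources used here. The deposited table does not state the base of the logarithm. Its highest value, 13.11, exceeds 11.1, the natural logarithm of the largest value a 16-bit scanner can record (65535), and the values were therefore read as log2. They ran from 0.58 to 13.11 over 32321 probe sets with none missing. Array medians lay between 4.26 and 4.36 in ICC, 4.23 and 4.40 in CHC, 4.24 and 4.25 in adenoma, 4.23 and 4.38 in FNH, and 4.24 and 4.39 in non-tumor liver. No detection calls or background levels were used here, so a low value cannot be read as absence, and the number of arrays limits the precision of each difference.

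A gene was named for 20546 probe sets. Of these, 19158 carried 1 symbol and 1388 carried several, and 11775 more carried none. The gene identifier of 19128 of the 1-symbol probe sets matched the GRCh38 gene table and that of 30 did not. XIST, TSIX and genes on the Y chromosome (24 probe sets) were left out. For each of the 636 genes with more than 1 probe set the brightest over all arrays was kept, which left 18381 genes. Probe sets without exactly 1 symbol were tested apart.

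Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust). All 5 groups stood in 1 fit with 32 residual and 3.2 prior degrees of freedom, tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each of the 8 comparisons. The spread of a gene was thus shared by all groups, so comparisons without ICC or CHC also carry the spread of those tumors. A gene was called at an adjusted p under 0.05. Each log2 difference is printed with its standard error after ±. No source used here says whether the samples of a group came from separate donors or whether non-tumor and tumor pieces came from the same people. The p-values therefore measure only the spread between these samples, part of which may be technical.

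Before the data were examined, 28 gene lists, the tests, the alternatives and the rule for naming genes were fixed. The lists were hepatocyte plasma proteins, drug and alcohol metabolism, bile acid synthesis and transport, urea cycle and amino acid catabolism, gluconeogenesis and glycogen, acute phase response, cholangiocyte markers, hepatic stem and progenitor markers, EMT (epithelial to mesenchymal transition) mesenchymal genes, epithelial junction genes, reported miR-200c targets, TGF-beta signalling, extracellular matrix and fibroblast genes, cell cycle genes, mucins and gastrointestinal epithelial genes, hypoxia and glycolysis, beta-catenin targets in liver, NF-kappaB and chemokine genes, sinusoidal endothelial, vascular endothelial, hepatic stellate cell, macrophage and Kupffer cell, T and NK cell, B and plasma cell, neutrophil, smooth muscle and red blood cell markers, and metallothioneins. They named 419 members, of which 385 were measured, 5 through an older symbol. They were written from general knowledge and not picked from these samples, and some genes stand in several lists. Each list was tested with limma's camera, a competitive test against all other genes, with a preset correlation between genes of 0.01, adjusted over the 28 lists. Beside it stood camera with the correlation estimated from the arrays (statmod 1.5.0) and limma's fry, which tests whether the genes of a set move on balance one way. Counts of members were also adjusted over the list alone.

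The rule named, for each comparison, up to 10 genes with the largest rise and up to 10 with the largest fall of at least 2-fold among those called. It added up to 4 called members of each list described, or up to 2 members as values where none was called, and the markers EPCAM, KRT19, KRT7, SOX9, PROM1, NCAM1, AFP, GPC3, CDH1, VIM, ZEB1, ZEB2, ALB and GLUL throughout. Members of list counts of 5 or fewer that the rule did not reach were named after their values were seen.

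A list score was the mean log2 value of the measured members on an array. Over the 16 ICC arrays, 6 relations between list scores fixed beforehand were tested with Pearson's r and Spearman's rho, each with a two-sided permutation p from 100000 resamples (scipy 1.17.1), adjusted over the 6. Principal components were taken over all genes tested. The calls shared by ICC and CHC were set beside 100 simulations of unchanged groups against the same controls and beside a fit in which non-tumor replicates 1 to 4 served ICC and 5 to 7 served CHC. For the comparisons of groups of at least 3, 100 splits of the same arrays into groups of the same sizes, the real split included, were fitted in the same way.

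The fit was tested on simulated data of 18381 genes with 200 changed and the group sizes used here. It recovered 78% of 2-fold and 99% of 4-fold changes for ICC against non-tumor, 84% and 95% for CHC against non-tumor, 87% and 98% for ICC against CHC, and 69% and 95% for FNH against non-tumor. For adenoma against non-tumor it recovered 44% and 89%, for ICC against FNH 77% and 96%, for CHC against FNH 75% and 96%, and for FNH against adenoma 38% and 90%. False calls made up between 1.67% and 7.25% of all calls. The simulated genes were independent and each had 1 SD in all groups. In the real arrays, weights per group ran from 0.68 (CHC) to 1.30 (non-tumor), so these rates hold for the simulated setting only.

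Alternatives fixed beforehand were arrays centred on their median, a repeat of quantile normalization, genes left out unless their mean reached 4.84 (the median over genes) in at least 1 group, a fit of the compared groups alone, eBayes with trend and robust, array weights with 1 variance per group, the mean of a gene's probe sets, every probe set as its own gene, an adjusted p under 0.01, and leaving out each array in turn. For the relations they were medians over members, members scaled to SD 1, median-centred arrays, a partial correlation given the plasma protein score, and leaving out the 2 arrays farthest from the median or each array in turn. After the data had been seen, fits without the 3 arrays of narrowest spread, with ICC replicates 3 and 4 averaged and with the array SD as a covariate were added, as were a partial correlation given the array SD, an EMT score without its matrix products (before that relation was computed), and leaving out each array for the shared calls. Summaries and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.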

Results

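Gene expression was measured on 37 whole-transcript arrays of human liver tissue, 1 array per sample. Intrahepatic cholangiocarcinoma (ICC, 16 arrays) is a cancer of the bile ducts within the liver, and combined hepatocellular and cholangiocarcinoma (CHC, 7 arrays) shows features of both hepatocytes and bile ducts. Hepatic adenoma (2 arrays) and focal nodular hyperplasia (FNH, 5 arrays) are benign lesions of hepatocytes, and 7 arrays came from non-tumor liver. The title of the series names a stem-like phenotype, epithelial to mesenchymal transition (EMT) and the microRNA miR-200c in ICC, and the lists of stem, EMT, epithelial and miR-200c target genes address these. Values are log2 intensities, differences are log2 differences ± standard error, and adjusted p-values are limma's. A count of arrays beside a gene, such as 15 of 16, gives the arrays past the mean of the other group, unless every array of that group is named.

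Malignant and non-malignant tissue fell apart along the first principal component, which held 41.2% of the variance. The 16 ICC arrays scored from -57.46 to -27.72 and the 7 CHC arrays from -48.48 to -8.07, whereas non-tumor liver scored from 48.07 to 81.43, FNH from 44.26 to 69.50 and the adenomas 57.28 and 57.38. The second component held 8.7% of the variance and correlated at r = 0.83 in absolute value, over all 37 arrays, with the SD of all probe sets of an array. The narrowest arrays by that SD were non-tumor replicate 4 (1.89), FNH replicate 2 (1.90) and CHC replicate 6 (1.94). Pairs of arrays correlated at a median r of 0.921 in ICC, 0.898 in CHC, 0.971 in FNH and 0.970 in non-tumor liver, across genes, which are not independent replicates.

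**Figure D1:**
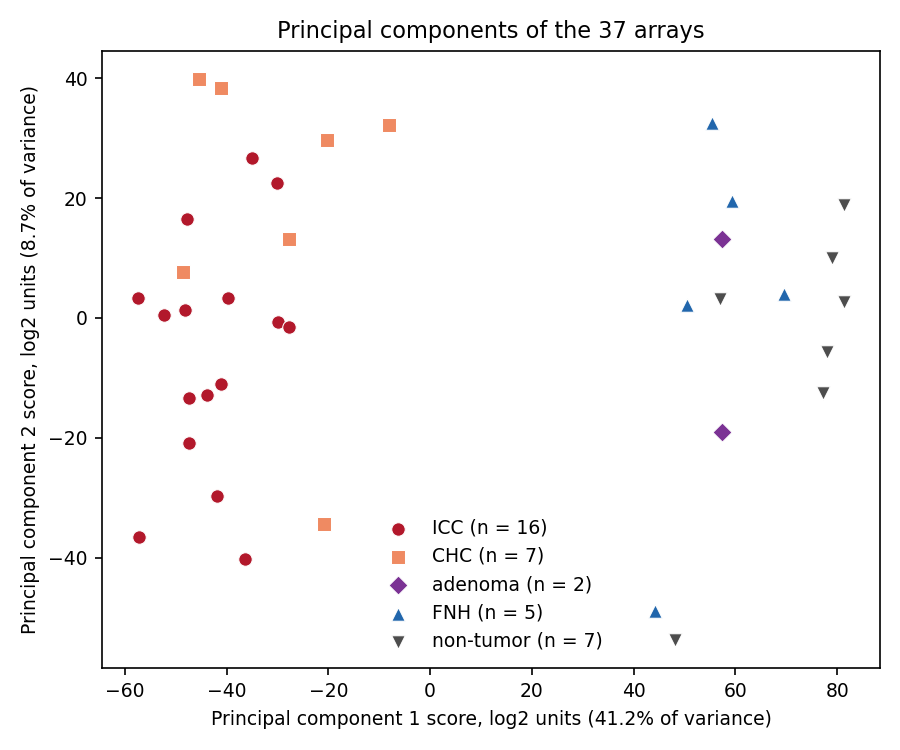
Scores of the 37 arrays on the first principal component (x axis, log2 units, 41.2% of variance) and the second (y axis, log2 units, 8.7% of variance), 1 point per array, coloured by group. All ICC and CHC arrays lie below -8.07 or at it on the x axis and all other arrays at 44.26 or above.

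The comparison of ICC with non-tumor liver asked which genes set the bile duct tumor apart from liver. Most listed genes of bile duct cells, of collagen-rich stroma and of dividing cells were higher in ICC, and those of hepatocytes, the sinusoidal endothelium and Kupffer cells were lower. The calls of the stroma, cell cycle and Kupffer cell lists were lost at adjusted p = 0.129, 0.175 and 0.129 with an estimated correlation. The secreted matrix protein osteopontin (SPP1, gene 6696, chromosome 4, 87975714 to 87983411 in GRCh38) rose most, by 5.75 ± 0.38 or 53.7-fold. Its level went from 4.91 ± 1.25 (SD, n = 7) to 10.66 ± 0.61 (SD, n = 16), with all 16 ICC arrays above every non-tumor array (adjusted p = 9.13e-15). Alcohol dehydrogenase 4 (ADH4, gene 127, chromosome 4, 99123658 to 99144297) fell by 7.46 ± 0.56 on the log2 scale. Its level went from 10.43 ± 0.38 (SD, n = 7) to 2.97 ± 1.51 (SD, n = 16), again in all 16 (adjusted p = 3.62e-13). In all, 3335 genes were higher and 2728 lower in ICC (6063 of 18381), and 2104 of them differed at least 2-fold. With arrays centred on their medians the larger share turned, to 3057 higher and 3244 lower.

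Hepatocyte genes fell across every function listed. Whole tissue does not tell a smaller share of hepatocytes from lower levels per cell, here and in CHC below, so the lists cannot be read as separate changes. All 20 measured plasma proteins were lower in ICC, as were all 16 genes of drug and alcohol metabolism and 15 of 16 of bile acid synthesis and transport. Also lower were all 14 of the urea cycle and amino acid catabolism, all 10 of gluconeogenesis and glycogen, and 11 of 12 of the acute phase response. No member of these lists was higher. Adjusted over the list alone, the counts were the same. The largest falls were those of ADH4, plasminogen (PLG, -7.03 ± 0.68), tyrosine aminotransferase (TAT, -7.02 ± 0.49), the drug-oxidizing CYP3A4 (-6.83 ± 0.75), the urea cycle enzyme CPS1 (-6.78 ± 0.73). Close to these were antithrombin (SERPINC1, -6.67 ± 0.44), coagulation factor IX (F9, -6.61 ± 0.35) and the gluconeogenic enzyme PCK1 (-6.54 ± 0.62), each in 16 of 16 arrays. Haptoglobin (HP, -6.26 ± 0.88), complement C9 (-6.11 ± 0.52) and the bile acid importer SLC10A1 (-5.91 ± 0.33) fell as well, and albumin (ALB) by 3.07 ± 0.71 in 16 of 16 arrays (adjusted p = 8.39e-04). Each of these 6 lists was also called with an estimated correlation, with adjusted p between 4.02e-04 and 0.0278.

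Of 15 cholangiocyte markers 14 rose and none fell (the same count adjusted over the list alone). The list kept its call with an estimated correlation (adjusted p = 0.0271). They included the epithelial adhesion molecule EPCAM (4.3 ± 0.82 in 14 of 16 arrays, adjusted p = 8.95e-05), CD24 (4.03 ± 0.39), DCDC2 (3.76 ± 0.71), the RNA-binding protein BICC1 (3.55 ± 0.62), the bile duct keratins KRT7 (2.78 ± 0.52) and KRT19 (2.75 ± 0.62) and the transcription factor SOX9 (1.12 ± 0.18). Hepatic stem and progenitor markers, which share EPCAM, KRT19, SOX9 and CD24 with that list, rose in 7 of 16 and fell in 2 (8 and 2 adjusted over the list alone), with adjusted p = 0.107 with an estimated correlation. PROM1 (2.35 ± 0.65) and THY1 (2.35 ± 0.32) rose in 15 and 16 of 16 arrays, whereas ANPEP (-0.94 ± 0.36) and SALL4 (-0.55 ± 0.19) fell in 13 and 14. The fetal liver genes AFP (-0.36 ± 0.31, adjusted p = 0.398, lower in 15 of 16) and GPC3 (1.34 ± 0.77, adjusted p = 0.184, higher in 13 of 16) were not called, nor was NCAM1 (0.35 ± 0.38, adjusted p = 0.501, higher in 7 of 16).

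Mesenchymal and epithelial genes were both higher in part. Of 16 EMT mesenchymal genes 7 rose and none fell (7 adjusted over the list alone), among them the intermediate filament vimentin (VIM, 1.88 ± 0.32), the matrix protein SPARC (1.59 ± 0.25), the collagen crosslinker LOX (1.5 ± 0.36) and the repressor ZEB1 (0.56 ± 0.19 in 15 of 16 arrays, adjusted p = 0.0183). For the list, adjusted p = 0.323 with an estimated correlation. ZEB2 differed by -0.05 ± 0.33 (adjusted p = 0.928, lower in 7 of 16). Of 17 epithelial junction genes 9 rose and 1 fell (10 and 1 adjusted over the list alone), with adjusted p = 0.233 with an estimated correlation. RAB25 (3.01 ± 0.48), the membrane protease ST14 (2.19 ± 0.33) and the transcription factor GRHL2 (1.84 ± 0.38) rose and the splicing factor ESRP2 fell (-0.92 ± 0.24). E-cadherin (CDH1) differed by 0.69 ± 0.35 (adjusted p = 0.130, higher in 14 of 16). Of 16 reported miR-200c targets 5 rose (ZEB1, the Notch ligand JAG1 by 2.58 ± 0.29, MSN by 1.36 ± 0.24, SUZ12 by 0.80 ± 0.23 and FHOD1 by 0.52 ± 0.13). A further 2 fell (the actin regulator CFL2, -1.73 ± 0.22, and KDR, -1.0 ± 0.36). Adjusted over the list alone 6 rose and 2 fell, and the list was not called (camera adjusted p = 0.123, and 0.457 with an estimated correlation).

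Of 20 extracellular matrix and fibroblast genes 17 rose and none fell (18 adjusted over the list alone), led by VCAN (4.24 ± 0.45), collagen COL1A1 (3.09 ± 0.33) and the fibroblast protease FAP (3.0 ± 0.46), with adjusted p = 0.129 with an estimated correlation. TGF-beta signalling rose in 11 of 18 (12 adjusted over the list alone), including the ligand TGFB2 (3.37 ± 0.44) and the target PMEPA1 (2.94 ± 0.36), with adjusted p = 0.0775 with an estimated correlation. Of 21 cell cycle genes 18 rose (20 adjusted over the list alone), such as TOP2A (2.17 ± 0.36) and PRC1 (1.96 ± 0.29), both in 16 of 16 arrays, with adjusted p = 0.175 with an estimated correlation. Hypoxia and glycolysis rose in 8 of 14, such as PKM (3.14 ± 0.20) and PFKP (2.15 ± 0.36), and fell in 1, the mitophagy gene BNIP3 (-1.85 ± 0.31), with adjusted p = 0.242 with an estimated correlation. NF-kappaB and chemokine genes rose in 10 of 15, such as CXCL8 (2.89 ± 0.58) and CCL20 (2.87 ± 0.62), and fell in 1, CXCL2 (-1.58 ± 0.41), with adjusted p = 0.175 with an estimated correlation. Mucins and gastrointestinal epithelial genes rose in 5 of 16, namely MUC13 (3.16 ± 0.89), CEACAM6 (3.12 ± 0.91), MUC1 (2.87 ± 0.65), LGALS4 (2.74 ± 0.53) and CDH17 (1.99 ± 0.77), with adjusted p = 0.332 with an estimated correlation. Adjusted over the list alone, the counts of these last 3 lists were the same.

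Beta-catenin targets of the liver mostly fell, with 7 of 13 lower and 1 higher (the same adjusted over the list alone), and adjusted p = 0.123 with an estimated correlation. The hepatocyte lists fell as well, so a change of this pathway cannot be told from a smaller share of hepatocytes, here and for ICC and CHC below. The glutamate transporter SLC1A2 (-4.01 ± 0.26), ornithine aminotransferase (OAT, -2.16 ± 0.39) and TBX3 (-1.41 ± 0.21) fell and LEF1 rose (1.77 ± 0.25). Glutamine synthetase (GLUL) differed by -0.26 ± 0.22 (adjusted p = 0.363, lower in 10 of 16). Only the brighter of the 2 probe sets named GLUL was read, here and below. By its number it stands among probe sets of chromosome 9 genes (TEK and FCN2), whereas GLUL lies on chromosome 1. Whether it reads GLUL itself was not tested. All 13 sinusoidal endothelial markers fell, such as FCN3 (-3.71 ± 0.26), OIT3 (-3.64 ± 0.22), CRHBP (-3.62 ± 0.18) and the scavenger receptor STAB2 (-3.37 ± 0.29), each in 16 of 16 arrays. This list kept its call with an estimated correlation (adjusted p = 0.00216). Of 12 macrophage and Kupffer cell markers 10 fell and none rose (10 and 1 adjusted over the list alone), such as CD5L (-3.48 ± 0.28), the lipopolysaccharide coreceptor CD14 (-2.81 ± 0.28) and MARCO (-2.39 ± 0.25), with adjusted p = 0.129 with an estimated correlation. All 8 metallothioneins, which bind zinc and copper, fell, MT1G by 4.35 ± 0.39 and MT1X by 3.76 ± 0.32 on the log2 scale, in 16 of 16 arrays (adjusted p = 0.00908 for the list with an estimated correlation).

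Without any 1 array, between 5261 and 6251 genes were called. Among the genes named, KDR lost its call without non-tumor replicate 3, 5, 6 or 7 (adjusted p from 0.0572 to 0.0817), SALL4 without non-tumor replicate 4 or 5 (up to 0.0554), ANPEP without any 1 of 15 arrays (up to 0.0897) and CDH17 without any 1 of 14 (up to 0.0713). ANPEP, SALL4 and CDH17 each lost it in 2 other settings as well (up to 0.169, 0.0650 and 0.0657).

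**Figure D2:**
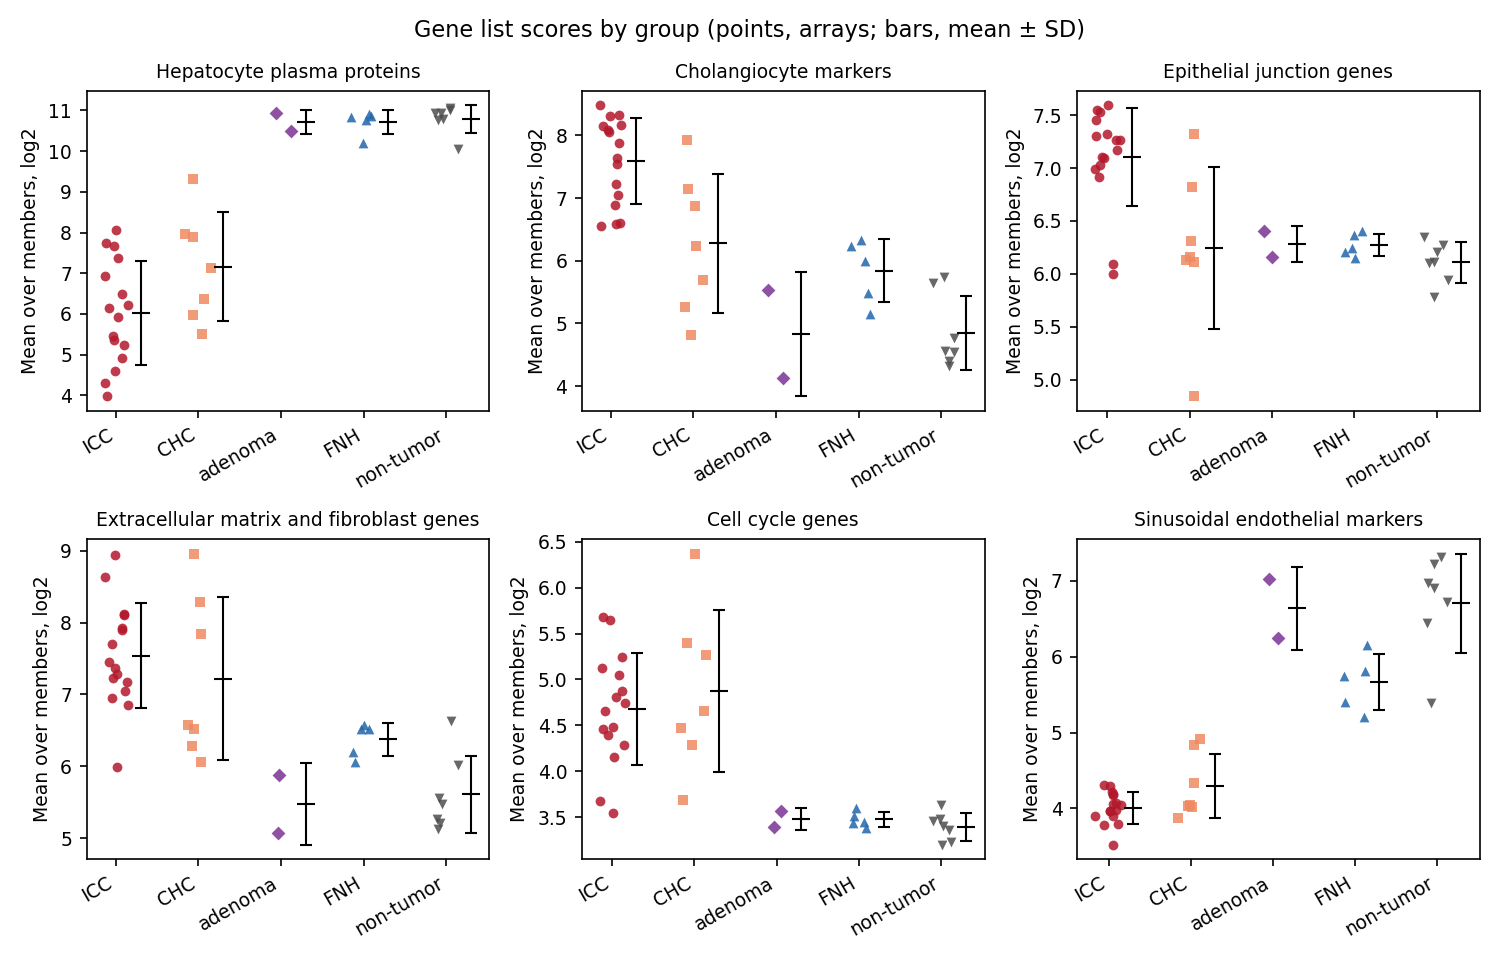
Scores of 6 gene lists (y axes, mean log2 value over the measured members) in the 5 groups (x axis), 1 point per array, with bars for mean ± SD. Plasma protein scores lie between 3.98 and 8.07 in the 16 ICC arrays, against a mean of 10.79 in non-tumor liver.

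CHC was compared with non-tumor liver to see what the combined tumor shares with ICC. SPP1 rose by 5.68 ± 0.44 in 7 of 7 arrays (adjusted p = 2.22e-12). The trypsin inhibitor SPINK1 (gene 6690, chromosome 5, 147824582 to 147839196) rose next, by 4.63 ± 1.07. It went from 2.67 ± 0.23 (SD, n = 7) to 7.30 ± 2.54 (SD, n = 7), above every non-tumor array in 7 of 7 (adjusted p = 0.00131). In all, 2737 genes were higher and 2309 lower (5046 of 18381), of which 1955 differed at least 2-fold. With arrays centred on their medians 2523 were higher and 2700 lower.

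Other large rises in CHC were those of VCAN (4.01 ± 0.53), MUC13 (3.87 ± 1.05), the epithelial oxidase DUOX2 (3.47 ± 0.93), the stromal protein periostin (POSTN, 3.46 ± 0.79), lysozyme (LYZ, 3.39 ± 0.66) and CD24 (3.38 ± 0.46). Cell cycle genes rose in 20 of 21 (21 adjusted over the list alone), with TOP2A at 2.29 ± 0.43 and PRC1 at 2.17 ± 0.34, and adjusted p = 0.154 with an estimated correlation. Hypoxia and glycolysis genes rose in 10 of 14 and fell in 1, BNIP3 (11 and 1 adjusted over the list alone), with PKM at 2.88 ± 0.24 and NDRG1 at 2.70 ± 0.43, and adjusted p = 0.152 with an estimated correlation. Matrix and fibroblast genes rose in 14 of 20 (15 adjusted over the list alone, adjusted p = 0.217 with an estimated correlation), with COL1A1 at 2.67 ± 0.38. TGF-beta signalling rose in 7 of 18 (8 adjusted over the list alone, adjusted p = 0.143 with an estimated correlation), with TGFB2 at 2.61 ± 0.52. EMT mesenchymal genes rose in 7 of 16 (7 adjusted over the list alone, adjusted p = 0.281 with an estimated correlation), with LOX at 2.25 ± 0.43, VIM at 1.82 ± 0.37 and ZEB1 at 0.81 ± 0.22.

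Hepatocyte lists fell in CHC with 15 of 20 plasma proteins, 15 of 16 genes of drug and alcohol metabolism, 15 of 16 of bile acid synthesis and transport and all 14 of the urea cycle and amino acid catabolism. All 10 genes of gluconeogenesis and glycogen were lower, and 10 of 12 of the acute phase response. Adjusted over the list alone, the plasma protein count was 18 and that of drug metabolism 16. ADH4 (-7.84 ± 0.66), CYP3A4 (-7.38 ± 0.89), TAT (-6.67 ± 0.57) and the iron hormone hepcidin (HAMP, -4.85 ± 0.43) fell in 7 of 7 arrays. ALB differed by -1.13 ± 0.83 (adjusted p = 0.318, lower in 6 of 7). Plasma proteins and the acute phase response each had adjusted p = 0.0710 with an estimated correlation, and the other 4 lists kept their calls. Sinusoidal markers fell in 10 of 13, such as FCN3 (-3.97 ± 0.30), and all 8 metallothioneins fell, such as MT1G (-4.16 ± 0.46). Both lists kept their calls with an estimated correlation (adjusted p = 0.00533 and 0.0111), with the same counts adjusted over the list alone.

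Only 4 of 15 cholangiocyte markers were called in CHC (SPP1, CD24, BICC1 at 2.06 ± 0.74 and ANXA4 at 0.97 ± 0.37), 6 adjusted over the list alone, with adjusted p = 0.210 with an estimated correlation. EPCAM differed by 1.48 ± 0.97 (adjusted p = 0.257, higher in 3 of 7), KRT19 by 1.48 ± 0.74 (adjusted p = 0.130, higher in 5 of 7) and KRT7 by 0.72 ± 0.61 (adjusted p = 0.388, higher in 4 of 7). Stem and progenitor markers rose in 4 of 16 (CD24, THY1, CD44 and ICAM1) and fell in 1, SALL4 (8 and 2 adjusted over the list alone), with adjusted p = 0.210 with an estimated correlation. AFP differed by 0.92 ± 0.37 (adjusted p = 0.0591, higher in 4 of 7) and GPC3 by 2.22 ± 0.91 (adjusted p = 0.0657, higher in 5 of 7). Epithelial junction genes rose in 2 of 17 (ST14 at 1.56 ± 0.39 and ELF3 at 1.15 ± 0.37) and fell in 2 (ESRP2, -1.38 ± 0.28, and CRB3, -0.48 ± 0.17), and the list was not called (camera adjusted p = 0.630). The neutrophil markers VNN2 (2.45 ± 0.42) and MNDA (1.39 ± 0.33) rose in 7 of 7 arrays, 2 of 9 of that list, with adjusted p = 0.402 with an estimated correlation.

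Leaving out single arrays gave between 4229 and 6400 genes. BICC1 lost its call without CHC replicate 1, 3 or 4 or non-tumor replicate 3, 5, 6 or 7 (adjusted p up to 0.108), ANXA4 without any 1 of 11 arrays (up to 0.155), ELF3 without CHC replicate 1 or 3 or non-tumor replicate 7 (up to 0.0657), CRB3 without any 1 of 5 (up to 0.101) and SALL4 without any 1 of 7 (up to 0.0669). In other settings, too, the calls of BICC1 (up to 0.0722), ANXA4 (0.228), ELF3 (0.0614), CRB3 (0.254) and SALL4 (0.140) were lost.

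Genes called in both tumors against non-tumor liver numbered 3993 in the same direction and 0 in opposite directions, of 6063 and 5046 called by limma. Independent lists of these sizes would share 839, and groups simulated as unchanged against the same controls shared a median of 0 and at most 2. With separate controls for the tumors, ICC (3908 called) and CHC (3364 called) shared 2172. Over all genes, which are not independent replicates, the differences correlated at r = 0.93, at 0.877 with separate controls and at a median of 0.616 in the simulations, where shared controls alone tie them.

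**Figure D3:**
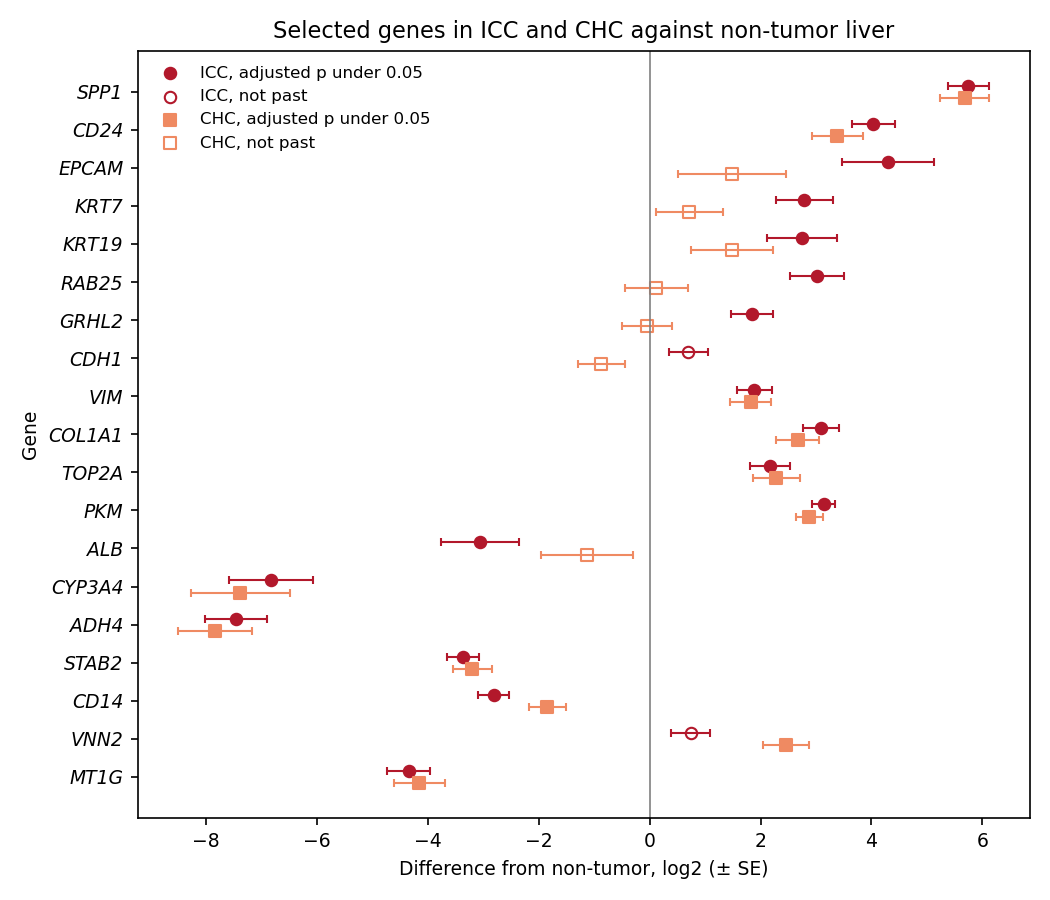
Difference from non-tumor liver of 19 named genes (x axis, log2 difference, bars ± SE) in ICC (circles) and CHC (squares), with filled symbols at an adjusted p under 0.05. EPCAM stands at 4.3 in ICC and 1.48 in CHC, and ADH4 at -7.46 and -7.84.

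The direct comparison of ICC with CHC asked where the pure and the combined tumor differ. Limma called 38 genes, 14 higher and 24 lower in ICC, 21 of them by at least 2-fold. The adhesion gene CEACAM7 (gene 1087, chromosome 19, 41673303 to 41688270) differed most, by 3.47 ± 0.70. It stood at 2.70 ± 0.35 (SD, n = 7) in CHC and 6.17 ± 2.35 (SD, n = 16) in ICC, above every CHC array in 13 of 16 (adjusted p = 0.0249). The endosomal GTPase RAB25 (2.90 ± 0.48 in 14 of 16 arrays, adjusted p = 0.00591), MACC1 (1.92 ± 0.44), GRHL2 (1.90 ± 0.38), the unconventional myosin MYO10 (1.72 ± 0.37) and E-cadherin (CDH1, 1.57 ± 0.35 in 15 of 16, above every CHC array in 9, adjusted p = 0.0474) were higher too. The guidance receptor ROBO1 (-1.90 ± 0.36), VNN2 (-1.72 ± 0.35), the phosphodiesterase SMPDL3A (-1.50 ± 0.27 in 16 of 16, adjusted p = 0.00793), the transcriptional coregulator CITED2 (-1.32 ± 0.25) and the lysosomal cholesterol carrier NPC2 (-1.02 ± 0.22) were lower.

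Epithelial junction genes were higher in 3 of 17 (RAB25, GRHL2 and CDH1; 8 adjusted over the list alone), with adjusted p = 0.0660 with an estimated correlation. Cholangiocyte markers were called in 0 of 15 by limma (9 higher adjusted over the list alone, adjusted p = 0.0660 with an estimated correlation), with EPCAM at 2.82 ± 0.82 (adjusted p = 0.124, higher in 14 of 16) and KRT7 at 2.07 ± 0.52 (adjusted p = 0.0808, higher in 15 of 16). Macrophage and Kupffer cell markers were likewise called in 0 of 12 (8 lower adjusted over the list alone, adjusted p = 0.0660 with an estimated correlation), with C1QB at -1.25 ± 0.33 (adjusted p = 0.0896, lower in 14 of 16). By fry these 3 lists passed, with adjusted p = 0.00847, 0.00847 and 0.00909. Plasma proteins were called in 0 of 20 (none adjusted over the list alone, adjusted p = 0.367 with an estimated correlation) and differed by a median of -1.21, with ALB at -1.94 ± 0.71 (adjusted p = 0.223, lower in 12 of 16). T and NK cell markers were called in 0 of 14 (3 lower adjusted over the list alone, adjusted p = 0.354 with an estimated correlation), and VNN2 alone was lower among 9 neutrophil markers (adjusted p = 0.479 with an estimated correlation). At an unadjusted p under 0.05 limma counted 2184 genes in this comparison.

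The count of 38 depended on the fit. A fit of the 23 ICC and CHC arrays alone called 0, weights with 1 variance per group called 5, and without the 3 arrays of narrowest spread 82 were called (14 higher, 68 lower), 31 of them among the 38. ICC replicates 3 and 4 averaged gave 23, and single arrays left out gave 13 to 121. The count fell to 20 to 25 without ICC replicate 1, 2, 3, 7, 8, 10 or 11 and to 13 and 14 without CHC replicates 2 and 5. It rose to 69 to 121 without ICC replicate 6, 12 or 15 or CHC replicate 1, 3 or 4. Of the 20 named genes called, 5 kept their calls without any 1 array (RAB25, SMPDL3A and CITED2 among them), and none of the 20 kept it in the fit of the 2 groups alone (adjusted p = 0.0888 for SMPDL3A, 0.0964 for RAB25 and 0.292 for MACC1). CEACAM7, GRHL2 and ROBO1 lost theirs without CHC replicate 2 (adjusted p = 0.0551), VNN2 without CHC replicate 2 or 5 (up to 0.0618), and CEACAM7 and GRHL2 also without CHC replicate 5 (0.0542). CDH1 and MACC1 lost theirs without any 1 of 15 arrays (up to 0.134 and 0.116), and MYO10 and NPC2 without any 1 of 9 (up to 0.107 and 0.116).

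FNH was compared with non-tumor liver as a benign lesion of hepatocytes. Limma called 13 genes, 2 higher and 11 lower, 12 of them by at least 2-fold, and 6 of 13 markers of the sinusoidal endothelium were lower. These calls use a spread taken over all 5 groups, ICC and CHC included. A fit of the FNH and non-tumor arrays alone called 3 genes, all higher, so no sinusoidal marker was called lower there. The lectin CLEC4M (gene 10332, chromosome 19, 7763243 to 7769605) fell by 2.70 ± 0.33 on the log2 scale, the largest fall. It went from 6.15 ± 1.23 (SD, n = 7) to 3.45 ± 0.10 (SD, n = 5), below every non-tumor array in 5 of 5 (adjusted p = 1.76e-05). STAB2 (-2.17 ± 0.38), OIT3 (-1.42 ± 0.29), the soluble lectin FCN2 (-1.37 ± 0.18), the histidine-degrading enzyme UROC1 (-1.63 ± 0.30) and the cholesteryl ester carrier CETP (-1.62 ± 0.27) fell, each in 5 of 5 arrays. The taurine transporter SLC6A6 (gene 6533, chromosome 3, 14402576 to 14489349) rose by 1.75 ± 0.28 in 5 of 5 arrays (adjusted p = 0.00183), and the pseudogene SLC26A10P rose by 1.16 ± 0.23.

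Sinusoidal markers fell in 6 of 13 (7 adjusted over the list alone), the single list of 16 called by camera here to keep its call with an estimated correlation (adjusted p = 3.97e-04). Macrophage and Kupffer cell markers were called in 0 of 12 (2 lower adjusted over the list alone, adjusted p = 0.233 with an estimated correlation), with CD5L at -1.17 ± 0.36 (adjusted p = 0.642, lower in 5 of 5). Red blood cell markers were called in 0 of 5 (1 lower adjusted over the list alone, adjusted p = 0.169 with an estimated correlation), with HBB at -1.61 ± 0.41 (adjusted p = 0.289, lower in 5 of 5). Cholangiocyte markers were called in 0 of 15 (1 higher adjusted over the list alone, adjusted p = 0.109 with an estimated correlation), with BICC1 at 2.29 ± 0.81 (adjusted p = 0.981, higher in 5 of 5). Matrix and fibroblast genes were called in 0 of 20 (4 higher adjusted over the list alone, adjusted p = 0.169 with an estimated correlation), with VCAN at 2.16 ± 0.58 (adjusted p = 0.401, higher in 5 of 5). Vascular endothelial markers were called in 0 of 12 (1 higher adjusted over the list alone, adjusted p = 0.233 with an estimated correlation), with CD34 at 1.33 ± 0.35 (adjusted p = 0.400, above every non-tumor array in 5 of 5). Limma called 0 of 20 plasma proteins (median difference -0.041, camera adjusted p = 0.742) and 0 of 10 genes of gluconeogenesis and glycogen (-0.248, camera adjusted p = 0.0982). It also called 0 of 16 genes of drug and alcohol metabolism (median -0.265) and 0 of 16 of bile acid synthesis and transport (-0.238), lists with adjusted p = 0.375 and 0.446 with an estimated correlation. Adjusted over the list alone, none of these 4 lists had a member called. Urea cycle and amino acid catabolism genes, with a median of -0.546, were called in 0 of 14 (2 lower adjusted over the list alone, adjusted p = 0.109 with an estimated correlation). Beta-catenin targets were called in 0 of 13 (1 higher adjusted over the list alone, adjusted p = 0.276 with an estimated correlation), with GLUL at 0.93 ± 0.28 (adjusted p = 0.573, higher in 5 of 5) and LGR5 at 1.11 ± 0.51. At an unadjusted p under 0.05 limma counted 600 of 18381 genes, fewer than the 1 in 20 that chance alone would give. The spread in this fit is shared by all groups, and ALB, for instance, had an SD of 2.33 in ICC, 0.32 in FNH and 0.24 in non-tumor liver. For such genes the standard error and adjusted p do not measure the spread of the arrays compared. A list with 0 members called here cannot be read as unchanged. A fit of these 12 arrays alone called 3 genes, all higher and 1 of them among the 13. SLC6A6 kept its call there, and CLEC4M, STAB2, OIT3, FCN2, UROC1, CETP and SLC26A10P lost theirs (adjusted p from 0.0754 for FCN2 to 0.301 for UROC1). The count was 8 without FNH replicate 5 and 25 without non-tumor replicate 4. OIT3 lost its call without FNH replicate 1, 2 or 5 or any 1 of 5 non-tumor arrays (adjusted p up to 0.209), SLC26A10P without any 1 of 5 arrays (up to 0.0916) and UROC1 without FNH replicate 4 (0.0843).

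The 2 adenomas were set against non-tumor liver and against FNH to compare the benign lesions. Against non-tumor liver limma called 33 genes, 12 higher and 21 lower, all by at least 2-fold. A fit of these 9 arrays alone called 26, 18 higher and 8 lower, with 9 among the 33. The acute phase protein SAA1 (gene 6288, chromosome 11, 18266264 to 18269967) rose by 4.97 ± 0.95. It went from 5.43 ± 1.25 (SD, n = 7) to 10.41 ± 1.04 (SD, n = 2), in 2 of 2 arrays (adjusted p = 0.00809). It was 1 of 12 called among acute phase genes (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.176). The vasopressin receptor AVPR1A (2.73 ± 0.40) and the kinase IP6K3 (2.46 ± 0.36) rose too. The caffeine-oxidizing CYP1A2 (gene 1544, chromosome 15, 74748845 to 74756607) fell by 4.01 ± 0.36 on the log2 scale. It went from 9.16 ± 0.69 (SD, n = 7) to 5.15 ± 0.54 (SD, n = 2), in 2 of 2 arrays (adjusted p = 1.17e-08). The noncoding CPS1-IT1 (-4.85 ± 0.84), the bile acid and drug importer SLCO1B3 (-3.96 ± 0.84), CYP3A43 (-3.83 ± 0.63) and apolipoprotein(a) (LPA, -2.97 ± 0.46) fell as well.

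Beta-catenin targets were lower in adenoma than in non-tumor liver in 2 of 13, OAT (-3.39 ± 0.68) and SLC1A2 (-2.92 ± 0.46), or 3 adjusted over the list alone, and the list kept its call with an estimated correlation (adjusted p = 0.00246), alone of the 8 lists called by camera here. GLUL differed by -0.34 ± 0.38 (adjusted p = 1.0, lower in 2 of 2). Neutrophil markers were called in 0 of 9 (3 higher adjusted over the list alone, adjusted p = 0.215 with an estimated correlation) and red blood cell markers in 0 of 5 (3 higher adjusted over the list alone, adjusted p = 0.194 with an estimated correlation). At an unadjusted p under 0.05 limma counted 1104 genes. The count was 71 without adenoma replicate 1 and 9 without adenoma replicate 2, where the lone adenoma is assumed to vary like the other groups, and 59 without non-tumor replicate 1. It was 55 without the 3 arrays of narrowest spread. SAA1, SLCO1B3 and OAT lost their calls without either adenoma (adjusted p up to 0.204, 0.717 and 0.264), as did AVPR1A, IP6K3, CPS1-IT1, CYP3A43 and LPA without adenoma replicate 2 (0.129, 0.397, 0.211, 0.790 and 0.279). In the fit of the 9 arrays alone the calls of OAT (adjusted p = 0.149), SLC1A2 (0.115), IP6K3 (0.146), CYP3A43 (0.128) and LPA (0.165) were lost.

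Against adenoma, FNH had 12 genes higher and 19 lower (31 called by limma, 30 by at least 2-fold). With arrays centred on their medians the split was 8 higher and 21 lower. CYP1A2 was higher in FNH by 3.81 ± 0.38 in 5 of 5 arrays (adjusted p = 1.48e-07), as were CPS1-IT1 (4.62 ± 0.88), SLCO1B3 (4.27 ± 0.88) and HGFAC (1.95 ± 0.25). Beta-catenin targets were higher in 2 of 13, SLC1A2 (2.19 ± 0.48) and the ammonium transporter RHBG (1.63 ± 0.35), or 9 adjusted over the list alone, and the list kept its call with an estimated correlation (adjusted p = 1.91e-04). LGR5 (2.40 ± 0.73, adjusted p = 0.341) and GLUL (1.26 ± 0.40, adjusted p = 0.396) were higher in 5 of 5 without being called. Lower in FNH were AVPR1A (-3.30 ± 0.41), IP6K3 (-2.81 ± 0.37), CETP (-2.08 ± 0.38), the hemoglobin genes HBB (-3.08 ± 0.58) and HBD (-1.02 ± 0.22), and the sinusoidal CLEC4M (-2.50 ± 0.47) and FCN2 (-1.16 ± 0.26). Red blood cell markers were lower in 2 of 5 (3 adjusted over the list alone) and kept their call with an estimated correlation (adjusted p = 0.0140). Sinusoidal markers were lower in 2 of 13 (7 adjusted over the list alone, adjusted p = 0.0542 with an estimated correlation). The count was 77 and 11 without adenoma replicates 1 and 2, 20 without FNH replicate 1 or 2, 16, 15 and 17 without FNH replicates 3, 4 and 5, and 18 in a fit of the 7 arrays alone, 4 of them among the 31. That fit kept the calls of CYP1A2, AVPR1A, SLCO1B3 and CLEC4M. It ended those of CPS1-IT1 (adjusted p = 0.0550), CETP (0.0934), HBB (0.0962), IP6K3 (0.0983), HGFAC (0.110), RHBG (0.155), HBD (0.198), FCN2 (0.265) and SLC1A2 (0.295). Of the genes named here only CYP1A2 and AVPR1A also kept their calls without any 1 array. The others lost theirs without at least 1 array, with adjusted p up to 0.681 (SLCO1B3).

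Each malignant tumor was also set against FNH, with a benign lesion in place of liver. Limma called 3185 genes for ICC (1630 higher, 1555 lower, 1423 by at least 2-fold) and 2264 for CHC (1126 higher, 1138 lower, 1208 by at least 2-fold). SPP1 rose by 4.70 ± 0.43 in 16 of 16 ICC arrays (adjusted p = 9.23e-11) and by 4.63 ± 0.49 in 7 of 7 CHC arrays (adjusted p = 5.75e-09). POSTN rose by 3.75 ± 0.76 and 4.26 ± 0.87, KRT19 by 2.91 ± 0.71 in ICC, and ADH4 fell by 7.28 ± 0.63 and 7.66 ± 0.72 on the log2 scale. Cell cycle genes rose in 17 of 21 in both, or 20 and 21 adjusted over the list alone, with adjusted p = 0.195 and 0.108 with an estimated correlation. Plasma proteins fell in 20 of 20 and in 14 of 20 (18 adjusted over the list alone), and kept their calls with an estimated correlation (adjusted p = 0.00525 and 0.0222). Beta-catenin targets fell in 8 of 13 and rose in 1, LEF1, in ICC (the same adjusted over the list alone). Lower were GLUL (-1.19 ± 0.24 in 16 of 16, adjusted p = 5.00e-04), LGR5 (-1.96 ± 0.45), RHBG (-1.61 ± 0.22) and SLC1A2 (-3.28 ± 0.29), and the list kept its call with an estimated correlation (adjusted p = 0.0126). In CHC 6 of 13 fell and 1 rose (7 and 1 adjusted over the list alone, adjusted p = 0.0165 with an estimated correlation), and GLUL differed by -0.70 ± 0.28 (adjusted p = 0.102, lower in 7 of 7). A fit of the CHC and FNH arrays alone called 1508.

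Within ICC, 6 relations between list scores were tested over the 16 arrays by permutation and adjusted over the 6. The EMT score rose with the matrix and fibroblast score (r = 0.903, p = 2.0e-05, adjusted p = 1.2e-04; rho = 0.879, p = 3.0e-05), with r = 0.771 without the 2 arrays farthest from the median. It also rose with the TGF-beta score (r = 0.654, p = 0.00794, adjusted p = 0.0238; rho = 0.553, p = 0.0290, adjusted p = 0.0871), but here r was 0.468 without the 2 farthest arrays and 0.434 without ICC replicate 8, so that this relation rests on those samples. The EMT score and the epithelial junction score gave r = -0.313 (permutation p = 0.232, adjusted p = 0.347; rho = -0.315, p = 0.235; r = -0.462 without the 2 farthest). EMT and stem scores gave r = 0.219 (permutation p = 0.421, adjusted p = 0.505; rho = 0.009, p = 0.978; r = -0.132 without the 2 farthest). Cell cycle and stem scores gave r = -0.371 (permutation p = 0.155, adjusted p = 0.310; rho = -0.356, p = 0.177; r = -0.216 without the 2 farthest). Cholangiocyte and plasma protein scores gave r = -0.064 (permutation p = 0.810, adjusted p = 0.810; rho = -0.071, p = 0.796; r = -0.005 without the 2 farthest). The labels give no batch within which these could be repeated.

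**Figure D4:**
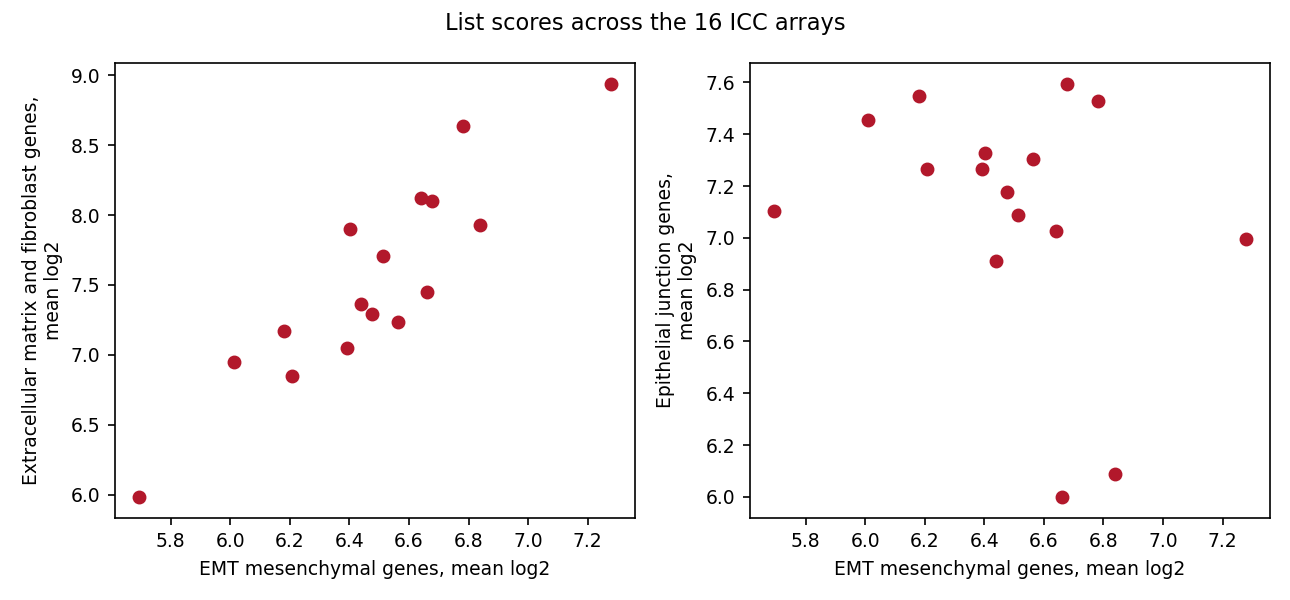
Score of EMT mesenchymal genes (x axes, mean log2 value) against the score of extracellular matrix and fibroblast genes (left) and of epithelial junction genes (right, y axes, mean log2 value) in the 16 ICC arrays, 1 point per array. The left relation has r = 0.903 and the right r = -0.313.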

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

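Of the tests below, those of the 3 arrays of narrow spread were chosen only after their spread was seen; the others were fixed before their results.

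In groups of 4 to 10 samples, the highest or lowest array was set apart from the others when its gap to the nearest was a large share of the range (Dixon's test). Of 456 combinations of a measure and a group, 51 (11.2%) had such an array, and chance alone gives about 1 in 20. Non-tumor replicate 4 accounted for 17, FNH replicate 2 for 9, non-tumor replicate 1 for 5 and CHC replicate 5 for 4. All values in the next 3 paragraphs are log2, with the nearest other array of the group in parentheses.

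Non-tumor replicate 4 was lowest for CPS1 at 10.07 (11.20), F9 at 6.80 (8.78), PCK1 at 9.69 (10.53), SLC10A1 at 7.09 (9.71), CDH1 at 7.20 (7.98), BNIP3 at 7.04 (7.92), FCN3 at 6.63 (8.50), CD5L at 4.87 (6.86), MARCO at 5.56 (6.57), CD14 at 8.04 (9.21), C1QB at 5.59 (6.95), CETP at 3.66 (5.38), ANPEP at 7.67 (8.50), RELN at 5.69 (7.40), ECM1 at 5.89 (6.27) and the plasma protein score at 10.06 (10.76), and highest for SOX9 at 6.15 (5.60). Non-tumor replicate 1 was highest for LOX at 4.32 (3.26), LGALS4 at 7.77 (6.60), HGF at 7.35 (5.97) and CD3G at 4.76 (4.05), and lowest for TBX3 at 5.40 (6.09). Non-tumor replicate 2 was lowest for DUOX2 at 2.68 (2.86).

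FNH replicate 2 was lowest for CPS1 at 9.94 (10.89), ALB at 11.61 (12.19), C9 at 8.55 (9.46), VNN2 at 2.36 (3.27), SMPDL3A at 5.00 (6.02) and the plasma protein score at 10.21 (10.75), and highest for MUC1 at 4.60 (3.78), FHOD1 at 4.92 (4.41) and ROBO4 at 5.86 (5.21). FNH replicate 1 was highest for CITED2 at 6.97 (6.36) and HBB at 6.27 (4.65). FNH replicate 3 was lowest for PKM at 6.49 (6.96) and ANXA4 at 7.82 (8.44) and highest for AVPR1A at 5.34 (4.03). FNH replicate 4 was highest for POSTN at 5.17 (3.17). FNH replicate 5 was highest for SPINK1 at 5.90 (2.46) and MYLK at 7.78 (7.36) and lowest for HBD at 3.41 (3.70).

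CHC replicate 5 was highest for the hepatocyte genes ADH4 at 6.46 (2.03), CYP3A4 at 8.24 (3.48) and SLC10A1 at 5.14 (3.62) and for BLK at 4.52 (3.80). CHC replicate 7 was highest for CPS1-IT1 at 8.36 (3.60) and SMPDL3A at 7.46 (6.16), CHC replicate 2 for SUZ12 at 8.09 (7.03), CHC replicate 3 for CEACAM6 at 5.01 (3.51), CHC replicate 4 for GRHL2 at 4.29 (3.22) and CHC replicate 6 for RHBG at 5.03 (4.27).

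Differences between groups under the same contrast were tested by limma as ICC against CHC, with 38 genes called, and as FNH against adenoma, with 31. Outside the genes compared, 13163 probe sets carry no symbol or several, and of these 997 were higher and 639 lower in ICC than in non-tumor liver at an adjusted p under 0.05 by limma, 310 of them higher by at least 2-fold.

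Hepatocyte genes varied among the 16 ICC arrays, with plasma protein scores from 3.98 to 8.07. If pieces of adjacent liver were taken along, the drug and alcohol metabolism score would rise with the pooled sinusoidal and Kupffer cell score. It did, with r = 0.573 over the 16 arrays (95% interval 0.108 to 0.832, permutation p = 0.0215). Spearman's rho was 0.641 (permutation p = 0.00932), and r was 0.57 without the 2 farthest arrays. This is consistent with adjacent liver in some pieces. For a loss of spread over the whole array, r with the array SD was 0.143 (permutation p = 0.602, interval -0.380 to 0.596), an interval too wide to decide, so that this explanation stays open. No biological explanation was tested.

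The EMT score also varied among the ICC arrays. The relation of EMT mesenchymal genes and extracellular matrix and fibroblast genes across ICC had r = 0.903 (interval 0.737 to 0.966, and 0.746 with matrix products left out of the EMT score), which is consistent with a differing share of stroma. With the matrix score held fixed, the EMT score fell as the epithelial junction score rose. The partial r was -0.611 (interval -0.855 to -0.143, permutation p = 0.00773), whereas the unadjusted r was -0.313. The partial rho was -0.612 (permutation p = 0.0138), and the partial r was -0.525 without the 2 farthest arrays. Tumor cells that trade epithelial for mesenchymal genes would give such a fall, but the test does not single them out. Any other cells that carry EMT genes and lack junction genes would give it too, and whole tissue leaves open which cells carry the transcripts. The partial p is not adjusted, and the relation without the matrix score was not called (permutation adjusted p = 0.347).

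The arrays of narrowest spread were 1 each of non-tumor liver, FNH and CHC. Their deviations from their group means, less the trend on mean level, correlated across genes with r between 0.268 and 0.777, and 97.0% of 404 other pairs of arrays from different groups lay below 0.268 (median 0.002, highest 0.541). A tissue difference particular to each group was predicted to leave these deviations unrelated, and their median r was 0.369. The 3 arrays were picked for their narrow spread, however, and the 404 other pairs were not. Narrowing that the removed trend does not capture could itself tie the deviations, so this test cannot decide against such a difference. A technical factor common to the 3 arrays and a tissue feature common to them cannot be told apart, since no batch is given in the labels used here.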

How the results depend on the processing

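Of the settings below, leaving out the 3 arrays of narrowest spread, averaging ICC replicates 3 and 4, the array SD as a covariate and single arrays left out for the shared calls were chosen after the data had been seen. Counts of genes for ICC and CHC against non-tumor liver and against FNH stayed within 1.5 times their values in all settings but those given here. Over all results and settings 20234 values were labelled unchanged, 1079 fell below the threshold, 85 rose past it, 97 moved and 3 reversed. A relation that was not called was labelled unchanged when it stayed uncalled, whatever its direction. The r of EMT and stem scores, for instance, went from 0.219 to -0.132 without the 2 farthest arrays. An adjusted p under 0.01, a stricter limit by construction, gave 2997 genes for CHC against non-tumor, 7 for ICC against CHC, 21 for adenoma against non-tumor, 1933 for ICC and 1186 for CHC against FNH, 9 for FNH against adenoma and 2501 shared by ICC and CHC. A fit of the compared groups alone takes the spread from those groups only. It gave 0, 3, 1508 and 18 for ICC against CHC, FNH against non-tumor, CHC against FNH and FNH against adenoma. For ICC against CHC, limma counted 2184 genes at an unadjusted p under 0.05 in the fit of all groups. For ICC against non-tumor the fit of these groups alone gave 6302 genes in place of 6063. The fit of all groups assumes 1 variance per gene, but array weights per group ran from 0.68 (CHC) to 1.30 (non-tumor). Weights with 1 variance per group gave 5 for ICC against CHC and 74 for adenoma against non-tumor, leaving out the 3 narrowest arrays 82 and 55, the array SD as a covariate 65 for adenoma, and averaging ICC replicates 3 and 4 gave 23 for ICC against CHC. Separate controls left 2172 shared genes, with fewer samples on each side. With an estimated correlation, 9 of 20 lists stayed called for ICC and 6 of 19 for CHC against non-tumor, and 0 of 15 for ICC against CHC. It was 1 of 16 for FNH and 1 of 8 for adenoma against non-tumor, 9 of 19 and 9 of 16 against FNH, and 2 of 10 for FNH against adenoma. Fry called 3, 1, 1 and 3 lists for ICC against CHC, FNH and adenoma against non-tumor, and FNH against adenoma. For ICC against CHC 9 lists were called with dim genes left out and 8 without the 3 narrowest arrays. The correlation of EMT and TGF-beta scores was 0.546 with medians, 0.515 with scaled members and 0.468 without the 2 farthest arrays. Without single arrays, counts ran from 13 (CHC replicate 2) to 121 (CHC replicate 3) for ICC against CHC, 8 (FNH replicate 5) to 25 (non-tumor replicate 4) for FNH, 9 (adenoma replicate 2) to 71 (adenoma replicate 1) for adenoma, and 11 to 77 (the same arrays) for FNH against adenoma, and that correlation from 0.434 (ICC replicate 8) to 0.720. APOA4 in adenoma against non-tumor was 2.55 and became -0.20 without adenoma replicate 1 and 5.30 without adenoma replicate 2. CEACAM20 was 1.97 and became -0.095 and 4.03. For CEACAM20, FNH vs adenoma, -2.05 became 0.014 and -4.11. Both transcripts thus stood higher in adenoma replicate 1 than in adenoma replicate 2. Except where the construction is named, the cause was not tested.

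Named genes called kept their calls in all settings other than single arrays left out in 110 of 119 for ICC and 89 of 109 for CHC against non-tumor, 0 of 20 for ICC against CHC, 1 of 12 for FNH and 8 of 20 for adenoma against non-tumor, 85 of 94 for ICC and 57 of 81 for CHC against FNH, and 4 of 23 for FNH against adenoma. Median-centring moved the median difference by -0.035 for ICC against non-tumor. No paired analysis was possible because no source used here links samples to donors. Signal over background was not measured here, so that differences among dim probe sets may be compressed. With dim genes left out, and so fewer genes tested, 4855 were called for ICC against non-tumor in place of 6063. Of these 4855, 4663 were among the 6063.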

Other observations

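Of the tests below, the splits of the arrays were chosen only after the counts had been seen.

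Markers of vessels, stellate cells, lymphocytes, muscle and blood were also compared. In ICC against non-tumor liver, 2 of 12 vascular endothelial markers rose (PLVAP at 1.11 and CD34 at 1.0) and 2 fell (TEK at -1.22 and ROBO4 at -0.35), the same adjusted over the list alone. Camera gave adjusted p = 0.956, with a median of -0.17, a mean of 0.08 and an upward test. Stellate cell markers fell in 5 of 10 (RELN at -2.95, CXCL12 at -1.45, HGF at -1.33, COLEC11 at -0.81 and LRAT; 5 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.113). T and NK cell markers fell in 2 of 14 (NKG7 at -0.73 and PRF1 at -0.68, the same adjusted over the list alone, camera adjusted p = 0.239). B and plasma cell markers fell in 1 of 10 (BLK at -0.47, the same adjusted over the list alone, camera adjusted p = 0.407), and red blood cell markers in 3 of 5 (HBB at -2.10, HBD at -0.30 and SLC4A1 at -0.25, the same adjusted over the list alone, camera adjusted p = 0.113). In non-tumor liver and ICC, BLK stood at 4.144 and 3.675, HBD at 3.95 and 3.65 and SLC4A1 at 3.29 and 3.04. All lay under 4.84, the median over genes, and whether these small falls reflect cell content was not tested. Smooth muscle markers rose in 2 of 7 (MYH11 at 1.27 and ACTG2; 2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.521). Limma called 0 of 9 neutrophil markers (none adjusted over the list alone, camera adjusted p = 0.480), where 7916 of all genes had an unadjusted p under 0.05. Single arrays left out ended the calls of COLEC11 (14 arrays, adjusted p up to 0.0994), ACTG2 (12, up to 0.0844), HBD (16, up to 0.129) and SLC4A1 (15, up to 0.161). The same held for ROBO4 (4, up to 0.104), HGF (non-tumor replicate 1, 0.0831) and LRAT (non-tumor replicate 3, 0.0538).

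In CHC against non-tumor liver, vascular markers rose in 4 of 12 (VWF at 1.58, CD34 at 1.35, PECAM1 at 1.33 and PLVAP at 1.09) and fell in 1 (ROBO4 at -0.41), or 4 and 2 adjusted over the list alone. That list had a median of -0.08, a mean of 0.27 and camera adjusted p = 0.562. Macrophage and Kupffer cell markers fell in 3 of 12 (CD5L at -3.64, MARCO at -1.99 and CD14 at -1.85) and rose in 1 (SLC11A1 at 1.11), the same adjusted over the list alone, with a median of 0.11, a mean of -0.54 and a downward camera test (adjusted p = 0.186). Stellate cell markers fell in 5 of 10 (CXCL12 at -2.54, ECM1 at -1.17, COLEC11 at -1.0, LRAT at -0.95 and NGFR at -0.73, the same adjusted over the list alone, camera adjusted p = 0.0764). T and NK cell markers rose in 2 of 14 (CD3G at 1.11 and CD2 at 1.0), and in none adjusted over the list alone (camera adjusted p = 0.188). B and plasma cell markers fell in 1 of 10 (BLK at -0.44, the same adjusted over the list alone, camera adjusted p = 0.759) and red blood cell markers in 1 of 5 (HBB at -1.23, the same adjusted over the list alone, camera adjusted p = 0.281). BLK was dim here too, at 4.144 in non-tumor liver and 3.705 in CHC. Smooth muscle markers fell in 1 of 7 (MYLK at -0.82; 1 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.562). In a fit of the 2 groups alone BLK, MYLK and HBB lost their calls (adjusted p = 0.107, 0.104 and 0.0589). Beta-catenin targets fell in 6 of 13 and rose in 1 (the same adjusted over the list alone, adjusted p = 0.152 with an estimated correlation). NF-kappaB and chemokine genes rose in 6 of 15 and fell in 1 (8 and 1 adjusted over the list alone, adjusted p = 0.327 with an estimated correlation). Mucins rose in 4 of 16 (MUC13, MUC1, KRT20 and LGALS4, the same adjusted over the list alone, adjusted p = 0.468 with an estimated correlation). Reported miR-200c targets rose in 6 of 16 and fell in 2 (7 and 2 adjusted over the list alone, camera adjusted p = 0.0665). Single arrays left out ended the calls of VWF (7 arrays, adjusted p up to 0.112), PECAM1 (CHC replicate 4, 0.0529), ROBO4 (8, up to 0.0974) and SLC11A1 (10, up to 0.0910). The same held for COLEC11 (9, up to 0.0993), NGFR (CHC replicates 2 and 7, up to 0.0639), MYLK (CHC replicates 2 and 7, up to 0.0677), CD3G (6, up to 0.113), CD2 (3, up to 0.0971), KRT20 (CHC replicates 3 and 7, up to 0.0696) and LGALS4 (9, up to 0.140).

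Each count of genes for groups of at least 3 was set beside 100 splits of the same arrays into groups of the same sizes, the real split included. For ICC against non-tumor 1 split, the real one, reached 6063 genes, and the highest other had 1295. For CHC against non-tumor it was 1, with 5046 and 2655, for ICC against FNH 1, with 3185 and 32, and for CHC against FNH 1, with 2264 and 1383. For FNH against non-tumor 4 splits reached 13, and the highest other had 19. For ICC against CHC 2 splits reached 38, the real one and 1 other, which gave 208, several times the real count. That points to a structure of the samples, and what it reflects was not tested. At a share under 0.05 a random grouping was excluded for ICC and for CHC, each against non-tumor liver and against FNH. For FNH against non-tumor and ICC against CHC the share was under 0.05 as well, but another split called more genes than the real one. Chance is therefore not excluded there. ICC replicates 3 and 4 correlated at r = 0.976 across genes, with the next pair of ICC arrays at 0.958.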
